A study of Drosophila melanogaster with 4 samples.

How the data were processed

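The series compared gene expression in heads of adult male fruit flies (Drosophila melanogaster, Oregon-R wild type) kept on food with levetiracetam or on normal food. Levetiracetam is an antiepileptic drug that binds the synaptic vesicle protein SV2A. The source labels of the treated channels call the flies unmated. Per the labels' protocols, flies were fed 5 mg/ml of the drug for 3 days, in vials of 30 flies. Before that they spent 7 days on normal food. RNA came from 8 pools of heads, which made up 4 parallel sets of 1 treated and 1 control pool. Each set was hybridised to 1 spotted cDNA array with 2 dyes, so the 4 arrays are 4 biological replicates. Levetiracetam RNA carried Cy5 in replicates 1 and 2 and Cy3 in replicates 3 and 4. The age of the flies is given inconsistently: 3 to 4 days in the sample labels and 7 to 10 days at the start of feeding in the design text. Some control labels give 2 to 3 days of growth after collection where the other labels give 10 to 11.

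Per the labels' protocols, slides were read on a GenePix 4000A scanner and quantified in GenePix Pro 6.0. The authors normalized each array by ratio in Acuity 4.0, ignoring in that step spots under 100 intensity units and under 2 times the background. They kept spots with under 3% saturated pixels, no bad or absent flag and a signal to noise of at least 2, and analysed spots present in at least 3 replicates with one-class SAM 3.0 and 100 permutations. The deposited values are log2 ratios of the 2 channels, with no value for a spot that failed these filters. The log2 scale was read from the values, which lie on both sides of 0 and reach 16.61, the log2 of a ratio of 100000. Intensities and background were not used here, so no filter on brightness or intensity-dependent normalization could be run.

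The direction of the deposited ratio is not stated. It was taken as Cy5 over Cy3 on every array, and the sign of replicates 3 and 4 was turned so that a positive value is higher with levetiracetam. This direction is called likely only because channel 1 is labelled Cy5 on every array, and the values do not settle it. The median was negative on all 4 arrays (-0.15, -0.16, -0.079 and -0.31 for replicates 1 to 4). Over spots within 3 of 0 on the log2 scale, the mean of the deposited ratio lay nearer to 1 than the mean of its inverse on all 4. A ratio that was never turned would give this. Replicates 3 and 4 each reach 16.61, so on these swapped arrays the outcome rests on leaving such spots out. Against that, the deposited ratios of arrays of opposite orientation correlated above 0, and 27.4% of features had 1 sign on all 4 arrays as deposited against 8.91% with the sign turned, as values already turned by the authors would give. Array offsets and trends over the slide may hold much of this. The shares were 21.8% and 10.7% with arrays centred, and 15.9% and 14.5% with a local median subtracted. The mean correlation of opposite orientation was 0.136, and 0.0322 with the local median subtracted. The other reading, in which the authors had already turned the swapped arrays, was run for the features, the gene lists and the named genes as an alternative called the values as deposited. Under it, the treatment mean and the dye orientation term exchange places. Whether the authors centred the arrays stays unknown, and no centring was added in the main setting.

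The array holds 27648 spots in 48 blocks. Neighbouring spots were averaged in pairs to 13824 features, because the probe table named the same gene for both spots in 7609 of the 7609 listed pairs. Gene names came from the platform annotation, matched by gene ID to the RefSeq gene table of the Release 6 assembly (used for names only), which changed no symbol. Of the spots, 15116 had 1 gene symbol, 102 had several and 12430 were not in the table and stay unnamed. Of the spots with 1 symbol, 14894 matched a gene ID and 222 kept the name of the platform. No feature with several symbols was named. No genome build is named in the sources used here, so no positions are given.

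The test was limma's one-sample fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) of the mean log2 ratio against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. It ran on features with a value on at least 3 arrays. A second fit added dye orientation as a term. Fixed gene lists were tested with camera at a preset correlation of 0.01, on gene means over the 1632 genes with a value on all 4 arrays, for lists with at least 5 such genes. A list's shift is its mean log2 ratio minus that of all these genes. The 24 named features are the 12 higher and 12 lower ones with the smallest p among features with 1 symbol, a value on all 4 arrays and the same sign on all 4, with 1 feature per gene and whether or not they passed the threshold. From each list, up to 4 members with the smallest p were open to be named, from means over all features of the gene. Groups, comparisons, gene lists, the naming rule and all alternatives other than those named as added later were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9.

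Alternatives covered the direction of the ratio, centring and scaling of arrays, filters on missing values, dye orientation as a covariate, each array left out, SAM, an unmoderated fit, a robust prior, array weights, other thresholds and rows of one gene averaged. For lists, an estimated correlation and fry were run. The trend prior was not run because the values carry no intensity. For lists, the filter to all 4 arrays is the main setting itself. In SAM the 16 sign patterns of the 4 arrays served as permutations, and false calls were counted by their median over patterns. That replaced the mean after results had been seen, because with the mean no call was made even in simulated data. Subtraction of a local or block median, single spots as rows, removal of spots over 3 on the log2 scale, cameraPR, and an estimated correlation on the values as deposited or with an array left out were added after seeing the data.

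The fit was tested on simulated data with the missing values and spread of the 3980 tested features and 200 changed features, 20 times. It recovered 13.3% of features changed 1.5-fold, 52.9% of those changed 2-fold and 88% of those changed 4-fold, with 3.52% false calls. The orientation term recovered 30% at 2-fold and 79% at 4-fold. The simulated features were independent, without array offsets, trends over the slide or a dye bias. These shares therefore need not hold for the real arrays. The number of arrays, 4, limits the precision of every value.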

Results

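Two-colour cDNA arrays measured transcript abundance in heads of adult male flies after 3 days on food with 5 mg/ml levetiracetam, an antiepileptic drug, against heads of flies kept on normal food. There were 4 arrays, each with 1 treated and 1 control pool of heads from a separate set of vials. Levetiracetam RNA was labelled with Cy5 in replicates 1 and 2 and with Cy3 in replicates 3 and 4. A value was present for 8040, 12608, 8286 and 9827 spots in replicates 1 to 4, which is 29.1%, 45.6%, 30.0% and 35.5% of the spots. Of the 13824 features, 2951 had a value on all 4 arrays and 1029 on 3, so 3980 were tested. Signed values are log2 ratios of levetiracetam over normal food in the likely direction of the deposited ratio, which the sources used here do not state.

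The first comparison asked which transcripts differed in abundance in the head after feeding with the drug. In the likely direction, dpr16, a member of the dpr family of neuronal immunoglobulin-domain proteins, had the largest mean ratio among the named features, at 2.36-fold higher with levetiracetam, while with the values as deposited it stood at -0.25 on the log2 scale and the largest was that of Obp59a at 0.70. Sodh1 and feo followed dpr16 by p, at 1.74-fold and 1.73-fold higher, and stood at 0.079 and 0.12 on the log2 scale as deposited. After adjustment over all features none of these differences passed. With limma, 0 of 3980 features passed adjusted p 0.05, and the smallest adjusted p was 0.42. SAM also called 0 features. At an unadjusted p under 0.05 there were 105 features, 76 higher and 29 lower with levetiracetam, where 199 would be met by chance. With dye orientation as a covariate there were 260, 172 higher and 88 lower, and with a local median over the slide subtracted 236, 151 higher and 85 lower. With the values as deposited, 0 features passed in limma and 20 in SAM at a false discovery rate of 0.05, or 0 where SAM's false calls were averaged by their mean, and the split at an unadjusted p under 0.05 turned to 18 higher and 743 lower. The median over the tested features was then -0.17, against 0.028 in the likely direction. Without replicate 4 the split was 41 higher and 115 lower, and without replicate 2 it was 139 higher and 26 lower, out of 165. No array was centred here, and the turned medians of replicates 1 to 4 were -0.15, -0.16, 0.080 and 0.31. Leaving out an array therefore moves all features together, and the split with them.

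The 12 features named as higher all had an unadjusted p under 0.05, and none passed adjusted p 0.05. The ratio of dpr16 (Dmel_CG12591) was 1.24 ± 0.33 on the log2 scale (SD, n = 4), with a 95% interval of 0.83 to 1.64 and a limma adjusted p of 0.42. It lay between 0.84 and 1.60 on the single arrays. With dye orientation as a covariate it was the only feature to pass, at a limma adjusted p of 0.0469. Sodh1, a sorbitol dehydrogenase, stood at 0.80 ± 0.19 (SD, n = 4), which is 1.74-fold. Miox, a myo-inositol oxygenase, stood at 0.66 ± 0.29, and CG9485, the fly's glycogen debranching enzyme, at 0.77 ± 0.46. Taldo, the transaldolase of the pentose phosphate pathway, had the smallest spread of the 12, at 0.46 ± 0.087, between 0.35 and 0.56 on the single arrays. Paics, an enzyme of purine synthesis, stood at 0.55 ± 0.24, and at 0.25 once the local median was subtracted. The cytochrome P450 gene Cyp28d1 stood at 0.65 ± 0.18, or 1.57-fold. The gene feo, which codes for a microtubule-associated protein of the cytokinesis spindle, stood at 0.79 ± 0.23, and at 0.53 with the local median subtracted. CG5793, CG7065, CG9360 and CG6908 had ratios of 0.71 ± 0.16, 0.71 ± 0.27, 0.50 ± 0.19 and 0.46 ± 0.13. The limma adjusted p of the 12 ran from 0.42 to 1.00.

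Of the 12 features named as lower, 5 had an unadjusted p under 0.05. CG5707 stood at -0.72 ± 0.43 on the log2 scale (SD, n = 4) and CG8654 at -0.49 ± 0.24. A feature of Obp59a, an odorant-binding protein, stood at -0.74 ± 0.85. Its values were -0.062 and -0.015 in replicates 1 and 2, and -1.13 and -1.74 in replicates 3 and 4, and the gene's other feature had a mean of 0.40. Without replicate 4 the first feature stood at -0.40. The DEAD-box RNA helicase bel stood at -0.40 ± 0.26. DopEcR, a membrane receptor for dopamine and ecdysteroids, stood at -0.40 ± 0.28, or -0.26 without replicate 2, and its other feature at -0.20. Among the remaining 7, unc-13, which primes synaptic vesicles for release, stood at -0.29 ± 0.20 and the mitochondrial ribosomal protein gene mRpS34 at -0.34 ± 0.26, or -0.22 without replicate 3. The serpin gene Spn77Ba stood at -0.25 ± 0.100. CG4409 and vnc had means of -0.38 and -0.31. Jhbp14 at -0.37 ± 0.47 and CG13784 at -0.40 ± 0.56 owed most of their mean to replicate 2, at -1.07 and -1.24, and stood at -0.14 and -0.12 without it. With the local median subtracted, CG13784 stood at -0.091 and unc-13 at -0.49. All 12 had a limma adjusted p of 1.00. With the values as deposited, the 24 named features lay between -0.34 and 0.70, and 11 of them had the opposite sign. The median over all tested features was then -0.17, without centring. Of the named features that turned negative, only dpr16 and CG9485 lay below that median.

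**Figure D1:**
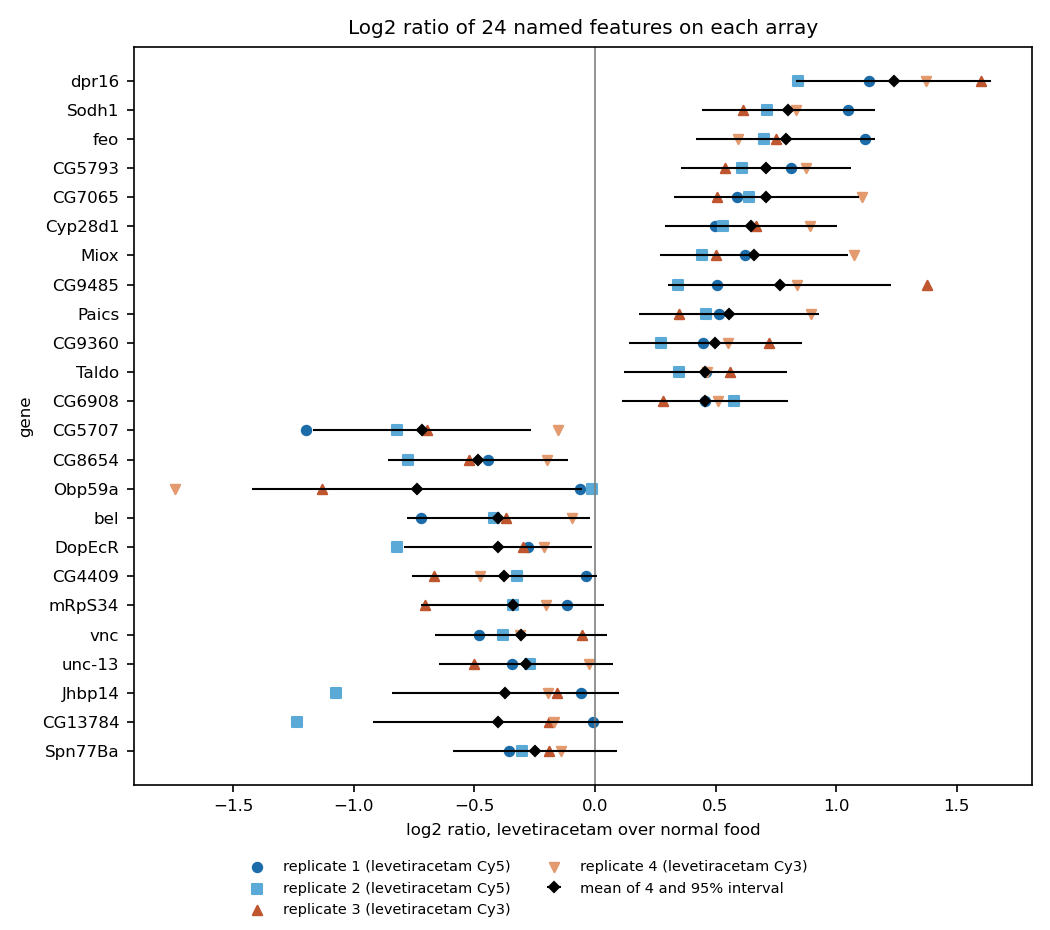
Log2 ratio of levetiracetam over normal food on the x axis for the 24 named features on the y axis, with a symbol for each of the 4 arrays, coloured by dye orientation. Black diamonds and lines are the mean and its 95% interval from limma, and dpr16 lies between 0.84 and 1.60 on the 4 arrays while none of the 24 passed adjusted p 0.05.

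The fixed gene lists asked whether pathways of the head shifted as a group. Of 29 lists, 21 had at least 5 genes on all 4 arrays, and camera called 0 of them at adjusted p 0.05. With an estimated correlation camera called 0, and fry called 0. Over all lists, 272 members were tested, counted once per list, and 0 passed adjusted p 0.05, both over all genes and adjusted over the list alone. Genes of glycolysis and trehalose metabolism lay above all genes by 0.12 ± 0.10 (SD over 4 arrays), on 3 of 4 arrays, with a camera adjusted p of 0.12 over the fit of all genes in limma. The measured members above 0 were 10 of 12, where 57.3% of all 2259 genes on at least 3 arrays lay above 0. As deposited, 3 of 12 members and 19.0% of these genes lay above 0. Pgi, glucose-6-phosphate isomerase, stood at 0.39 and the glycogen synthase gene Glys at 0.59 on 3 arrays. UGP, which makes the sugar donor for glycogen, stood at 0.35 on 3 arrays, and Gapdh1 at 0.25. Without replicate 4, Glys was 0.36 and Gapdh1 0.16. The shift of the list was 0.041 with the values as deposited, with a camera adjusted p of 0.70. With cameraPR on the 12 genes present on at least 3 arrays this list had an adjusted p of 0.0258. On its 9 genes present on all 4 arrays, with an estimated correlation, its camera adjusted p was 0.97. Detoxification enzymes had 20 of 24 measured members above 0, with a shift of 0.063 ± 0.063 over 4 arrays and a limma camera adjusted p of 0.74. The shift was 0.10 without replicate 4, and as deposited it was 0.038 with 8 of 24 members above 0. Cyp28d1 led this list, followed by Cyp4e2 at 0.66 on 3 arrays, which was 0.38 without replicate 3 and 1.09 without replicate 2.

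Genes of cytoplasmic ribosomal proteins lay above all genes by 0.11 ± 0.24 (SD over 4 arrays), on 2 of 4 arrays, with a limma camera adjusted p of 0.12. Of 14 measured members 12 were above 0, or 7 as deposited. Of all genes on at least 3 arrays, 57.3% lay above 0, or 19.0% as deposited. RpL23 at 0.46 and RpL15 at 0.33 had the smallest p, and RpL15 was 0.21 without replicate 4 and -0.12 as deposited. The shift of the list was 0.22 and 0.38 in replicates 1 and 2, and -0.16 and -0.020 in replicates 3 and 4. With the values as deposited this list passed, at a shift of 0.19 and a camera adjusted p of 0.0136, and its adjusted p was 0.82 with an estimated correlation. Without replicate 3 the shift was 0.20 and passed at a camera adjusted p of 0.00472, which was an adjusted p of 0.95 with an estimated correlation, while without replicate 2 it was 0.014, with an adjusted p of 0.80, and without replicate 1 it was 0.065, with an adjusted p of 0.64. Mitochondrial ribosomal proteins had a shift of 0.021 ± 0.17, proteasome subunits of 0.060 ± 0.14, and factors of translation initiation and elongation of -0.041 ± 0.12. With the local median subtracted that of the proteasome was 0.0066, and with cameraPR 0.14. Genes of oxidative phosphorylation had a shift of -0.012 ± 0.091, with 14 of 26 measured members above 0, or 7 as deposited. The limma camera adjusted p of these 4 lists lay between 0.78 and 0.88.

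Among neuronal lists, genes of monoamine synthesis, transport and reception lay below all genes on 4 of 4 arrays, by -0.16 ± 0.16 (SD), with a limma camera adjusted p of 0.10. With the values as deposited, where replicates 3 and 4 are not turned, they lay below only in replicates 1 and 2. Of 8 measured members 7 were below 0, or 8 as deposited. Of all genes on at least 3 arrays, 57.3% lay above 0 in the likely direction and 19.0% as deposited. The count as deposited therefore says little about these genes. DopEcR stood at -0.30 over both its features, and speck, an arylalkylamine N-acetyltransferase, at -0.24, which were -0.15 and -0.14 without replicate 2. The adjusted p of this list was 0.97 with an estimated correlation, and the shift was -0.39 in replicate 2 against -0.16 or nearer to 0 on the others. Without replicate 2 the shift was -0.088. With the local median subtracted it was -0.053, and with the values as deposited -0.064, with an adjusted p of 0.64.

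Genes of the synaptic vesicle cycle, the process in which the drug's target SV2A takes part in mammals, had a shift of -0.046 ± 0.096, with 5 of 10 measured members above 0, or 1 as deposited, where 19.0% of all genes on at least 3 arrays lay above 0. The shift was -0.18 in replicate 2, and -0.0020 without that array or -0.0034 with the local median subtracted. Synj, the phosphatase synaptojanin, stood at 0.42 on 3 arrays and at 0.17 without replicate 4 or 0.70 without replicate 2. Over both its features unc-13 stood at -0.21, and at -0.14 without replicate 3 or -0.35 without replicate 4. Channel genes had a shift of -0.013 ± 0.15, or -0.10 with the local median subtracted, with Teh1, an auxiliary sodium channel subunit, at 0.51 and the calcium channel gene Ca-alpha1D at -0.28. Without replicate 4 these were 0.26 and -0.45, and Ca-alpha1D was -0.16 without replicate 1. Genes of GABA and glutamate signalling had a mean shift of 0.024 ± 0.18 while camera's direction and the list's median of -0.030 were below 0. The glutamine synthetase gene Gs1 stood at 0.44, and between 0.16 and 0.68 with 1 array left out, lowest without replicate 3 and highest without replicate 2. The transporter gene Eaat2 stood at 0.26, and between 0.11 and 0.40, lowest without replicate 4 and highest without replicate 1. The neuropeptide list had a shift of 0.0099 ± 0.054, with amn, a neuropeptide gene of memory, at 0.44, or 0.29 without replicate 3. The receptor gene AkhR stood at -0.28, which rested on replicate 1 at -0.97 and was -0.053 without it, or -0.44 without replicate 3. Lists for phototransduction and the circadian clock had shifts of 0.029 ± 0.12 and -0.066 ± 0.066, and that of the clock was -0.037 without replicate 3 and -0.019 without replicate 4. The limma camera adjusted p of these 6 lists lay between 0.87 and 0.96.

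Markers of other tissues that a head sample can hold gave no call. Fat body markers had a shift of 0.036 ± 0.13 (SD over 4 arrays) and muscle markers of 0.16 ± 0.21, with adjusted p of 0.88 and 0.74 in limma's camera. The muscle shift was 0.019 without replicate 3, where Zasp66, a gene of the muscle Z-disc, stood at 2.43, and 0.042 with cameraPR. Apoltp, a lipid transfer particle apolipoprotein, stood at 0.76 on 3 arrays, and bmm, a triglyceride lipase, at 0.46, or 0.27 without replicate 4. Cuticle proteins had a shift of 0.038 ± 0.13, with Cpr67Fa1 at -0.56 and Cpr64Aa at -0.53, on 3 arrays each. Odorant-binding proteins had a shift of 0.00076 ± 0.18, heat shock proteins of 0.031 ± 0.17, antioxidant enzymes of 0.042 ± 0.092 and vacuolar ATPase subunits of 0.068 ± 0.073, or 0.036 without replicate 4. The limma camera adjusted p of these 5 lists lay between 0.78 and 0.87. The other 8 lists had under 5 genes on all 4 arrays and were not tested as lists. Measured members above 0 were 1 of 3 for acetylcholine signalling, 2 of 6 for glia, 3 of 4 for gut, 2 of 4 for immune genes, 2 of 2 for olfactory and gustatory receptors, 1 of 1 for histones and 2 of 2 for actin and tubulin. As deposited these were 0, 1, 3, 1, 1, 0 and 0, where 19.0% of all genes on at least 3 arrays lay above 0. Of the 10 testis and accessory gland markers on the array, 0 could be tested.

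**Figure D2:**
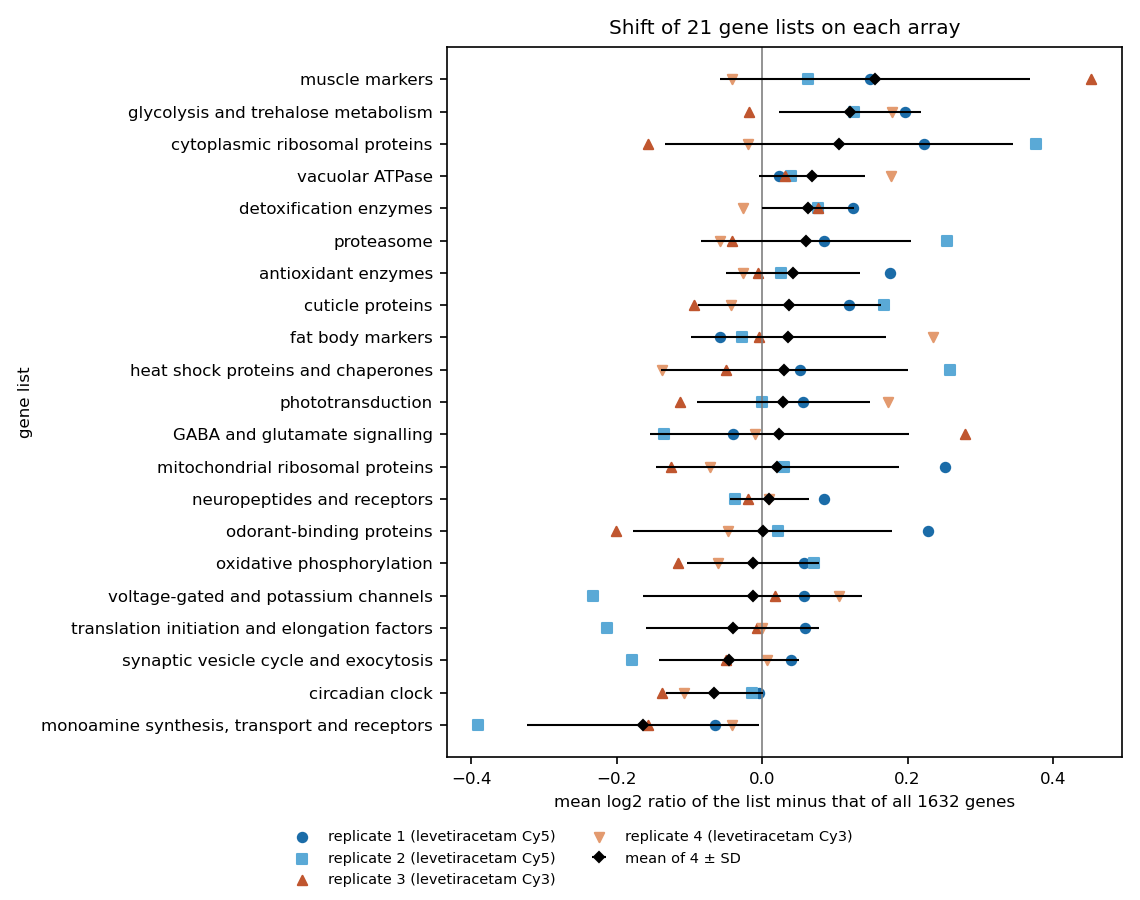
Mean log2 ratio of each of 21 gene lists minus that of all 1632 genes on the x axis, with a symbol for each of the 4 arrays and black diamonds and lines for the mean and SD over arrays. Genes of monoamine synthesis, transport and reception lie below 0 on 4 of 4 arrays with a mean of -0.16, and 0 of 21 lists passed adjusted p 0.05. With the values as deposited the mean of the monoamine genes is -0.064, and they lie below 0 in replicates 1 and 2 only.

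The last comparison asked how the 2 dye orientations differed, since under the other reading of the deposited values this term is the treatment effect. In limma the orientation term passed adjusted p 0.05 for 52 of 3980 features, 50 of them negative and 2 positive, and 787 had an unadjusted p under 0.05. The 2 positive terms were those of CG13313 at 1.11 and Mst77F at 1.26, named here after their values were seen. The median term of the 52 was -1.10. None passed once each array was centred on its median. With an array left out, 1 orientation rests on a single array, so counts from such fits cannot be set against the 52. Across features, the deposited ratios correlated at a Pearson r of 0.23 between replicates 1 and 2 and of 0.20 between replicates 3 and 4, which share an orientation. Between arrays of opposite orientation r was 0.10, 0.15, 0.19 and 0.10, and these turn negative when the swapped arrays are turned. Features are not independent replicates, and no p is given. Of the 2951 features on all 4 arrays, 210 were higher and 53 lower with levetiracetam on all 4, together 8.91%. With the values as deposited 63 were higher and 745 lower, together 27.4%. With arrays centred these shares were 10.7% (188 higher, 128 lower) and 21.8% (408 higher, 235 lower). With the local median subtracted they were 14.5% (240 higher, 188 lower) and 15.9% (287 higher, 181 lower). Chance gives 12.5% for arrays without an offset.

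**Figure D3:**
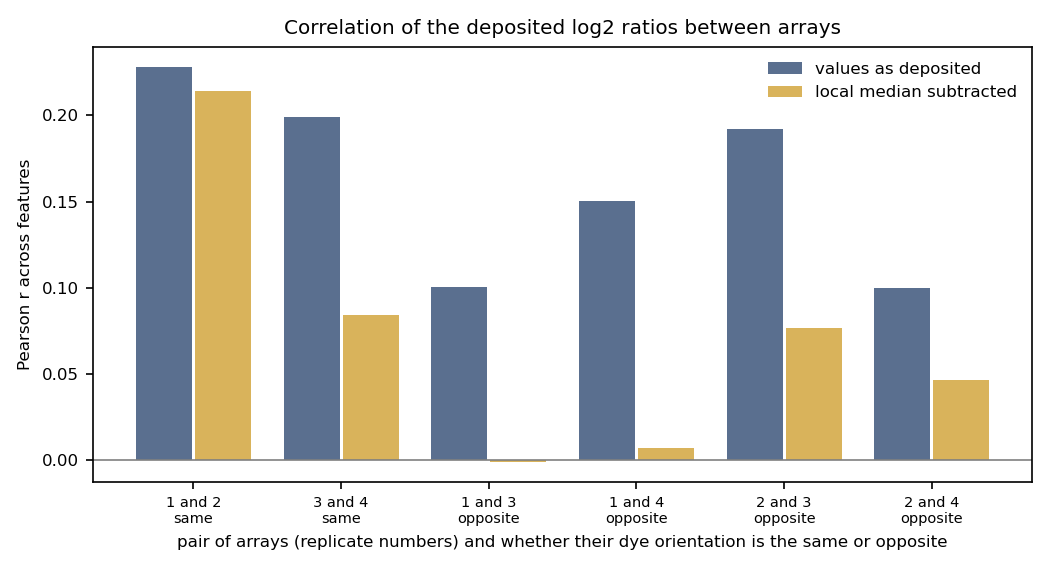
Pearson r across features, on the y axis, of the deposited log2 ratios for the 6 pairs of arrays on the x axis, as deposited and with a local median subtracted. The pair of replicates 1 and 2 keeps the highest r, 0.23 as deposited and 0.21 after subtraction, and the 4 pairs of opposite orientation lie between 0.10 and 0.19 as deposited.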

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

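The tests of the orientation term, of related neighbours, of correlations between orientations and of a local median without the feature's own row were chosen after their results were seen. Among the named features, 3 held 1 array far from the other 3, all in replicate 2 for a lower value: DopEcR at -0.82, Jhbp14 at -1.07 and CG13784 at -1.24. The vacuolar ATPase list held replicate 4 apart, at 0.18 against 0.024 to 0.040 on the other arrays. These were 4 of 65 sets of 4 values tested, and chance alone marks about 1 in 20, or 3.25.

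The dye orientation term passed for 52 features, a difference between the 2 orientations. They lay in 22 of the 48 blocks, where a draw of as many tested features fills 30 in the median, and 22 of the 52 lay in the 3 fullest blocks. Centring ended every call but left 83.1% of their median term (-1.10 with a median SE of 0.18 before, -0.91 and 0.16 after). It moved the median term of all features from -0.17 to 0.0069. As the 52 were chosen for large terms, a large remainder was bound to be left. The 83.1% therefore cannot decide for or against an offset of each whole array. The smallest adjusted p over all features was then 0.0963, and why the calls ended was not tested. A local median left 53.7% (-0.59, SE 0.14) and a block median 74.3% (-0.82, SE 0.15), so trends over the slide surface may account for part of it and cannot be told apart from the rest on 2 arrays per orientation. A drug effect, which this term would be if the authors had already turned the swapped arrays, stays open.

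Neighbouring spots of different features correlated at a mean Spearman rho of 0.351 within an array, close to the 0.439 of the 2 spots of one feature. With a local median subtracted the first stood at 0.106 and the second at 0.335. That median takes in the neighbours, and with each feature's own row left out of it the first stood at 0.207, so how much of the correlation comes from trends over the slide surface stays open. Features 1 row apart correlated at 0.373 against 0.427 side by side, which argues against related genes printed side by side, since that would not reach across rows. No biological explanation was tested.

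Arrays of one orientation correlated at a mean r of 0.214 and arrays of opposite orientation at 0.136. If the dye-swapped values were already turned by the authors, the inverted ratio should have its mean nearer to 1 on both swapped arrays, and this was so on 0 of 2. A real asymmetry in the treatment effect could give the same. The correlations of all 4 pairs of opposite orientation were above 0 as deposited, which goes with values already turned. With the local median subtracted they were -0.0012, 0.0066, 0.077 and 0.047. These values do not separate the 2 readings, and the direction used rests on the channel labels. With the local median subtracted the difference between the 2 means was 0.117 with a standard error of 0.0676, against 0.0781 before, too wide over 6 pairs to decide for or against trends over the slide surface. A gene-specific dye bias would also give positive correlations across orientations and was not tested.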

How the results depend on the processing

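Local and block medians, single spots, spots over 3 left out and cameraPR were chosen after seeing the data. The cause of each change below was not tested, except where fewer features or arrays enter. The count of features past adjusted p 0.05 was 0 in limma under every alternative but dye orientation as a covariate, with 1, and the thresholds of unadjusted p 0.01, with 27, and 0.05, with 105. SAM gave 0, and with the values as deposited 20, or 0 where false calls were averaged by their mean. In the likely direction SAM called 3 with local medians subtracted and 1 with arrays centred, or 0 and 0 by the mean. Features at an unadjusted p under 0.05 numbered 761 with the values as deposited, 173 with arrays centred, 176 with arrays scaled to one spread, 260 with orientation as a covariate, 236 with local and 200 with block medians subtracted and 229 with single spots as rows. They ranged from 71 to 165 with one array left out, which unbalances the dyes and the uncentred array medians. The orientation count was 12 on features of all 4 arrays, 0 with centring, local or block medians, and 0 to 212 with one array left out. Mean correlations with local medians were 0.149 for the same and 0.0322 for opposite orientation. Lists called numbered 1 with the values as deposited (cytoplasmic ribosomal proteins), 1 with cameraPR (glycolysis and trehalose metabolism) and 0 to 1 with one array left out (cytoplasmic ribosomal proteins, without replicate 3). With an estimated correlation, run after seeing the data for these settings, camera gave adjusted p of 0.82 for the first, 0.95 for the last and 0.97 for glycolysis on its 9 genes on all 4 arrays, so 0 lists were called. That correlation was estimated from 4 arrays at most. In the main setting it ran from -0.19 for muscle markers to 0.68 for vacuolar ATPase, so these adjusted p decide little.

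Among the named features, dpr16 alone changed its side of the threshold, with dye orientation as a covariate. They were chosen for 1 sign on all 4 arrays, so leaving out an array could not turn it, and that their sign held in settings other than the values as deposited says little about stability. With the values as deposited the sign turned for dpr16 (-0.25), CG7065 (-0.096), Cyp28d1 (-0.13), Miox (-0.13), CG9485 (-0.34), Paics (-0.067), CG9360 (-0.14), Taldo (-0.054), Obp59a (0.70), CG4409 (0.20) and mRpS34 (0.11). Of list members it turned for Glys (-0.36), UGP (-0.28), Gapdh1 (-0.12), RpL15 (-0.12), Cyp28d1 (-0.13), Cyp4e2 (-0.79), Synj (-0.50), Teh1 (-0.42), Gs1 (-0.50), Eaat2 (-0.36), amn (-0.20), Apoltp (-0.53), bmm (-0.28), mRpL54 (-0.41), eIF3g1 (-0.00025), Obp19b (0.12) and Zasp66 (-0.76). Of the 28 list members run through the settings, none turned in any other setting. They were chosen for a small p, and several settings share the main mean, so this says little about stability. With the values as deposited the median over all tested features was -0.17, without centring. A value between that and 0 therefore does not show a gene lower than most.

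List shifts turned sign with the values as deposited for GABA and glutamate (-0.11), phototransduction (-0.00097), clock (0.056), muscle (-0.050), fat body (-0.079), oxidative phosphorylation (0.076) and vacuolar ATPase (-0.036). With local medians they turned for GABA and glutamate (-0.017), heat shock (-0.047), oxidative phosphorylation (0.018), mitochondrial ribosomal (-0.010) and cuticle proteins (-0.046). With block medians they turned for heat shock (-0.031), oxidative phosphorylation (0.00487) and odorant-binding proteins (-0.017), with scaling for odorant-binding proteins (-0.000188), and with cameraPR for antioxidant (-0.059), cuticle (-0.11) and odorant-binding lists (-0.00967). With one array left out the ranges that crossed 0 were -0.050 to 0.041 for channels, -0.056 to 0.062 for GABA and glutamate, -0.00610 to 0.025 for neuropeptides, -0.015 to 0.082 for phototransduction, -0.017 to 0.12 for fat body, -0.046 to 0.091 for heat shock, -0.070 to 0.069 for antioxidants, -0.047 to 0.029 for oxidative phosphorylation, -0.045 to 0.061 for mitochondrial ribosomal, -0.00527 to 0.16 for proteasome, -0.10 to 0.016 for translation factors, -0.056 to 0.094 for cuticle and -0.088 to 0.073 for odorant-binding proteins. Ranges that kept their sign were -0.21 to -0.088 for monoamines, -0.059 to -0.0020 for the synaptic vesicle cycle, -0.084 to -0.019 for the clock, 0.019 to 0.19 for muscle, 0.058 to 0.10 for detoxification, 0.11 to 0.17 for glycolysis, 0.014 to 0.20 for cytoplasmic ribosomal proteins and 0.036 to 0.086 for vacuolar ATPase. With the values as deposited, shifts that kept their sign and differed by over 1.5 times were those of the synaptic vesicle cycle (-0.024), channels (-0.075), monoamines (-0.064), detoxification (0.038), heat shock (0.12), glycolysis (0.041), cytoplasmic (0.19) and mitochondrial ribosomal proteins (0.12), proteasome (0.11), cuticle (0.11) and odorant-binding proteins (0.12). Of all these, cytoplasmic ribosomal proteins alone passed, without replicate 3 and with the values as deposited, and in neither with an estimated correlation (adjusted p 0.95 and 0.82). Further shifts that kept their sign and differed by over 1.5 times were, with local medians, those of the synaptic vesicle cycle (-0.0034), channels (-0.10), monoamines (-0.053), neuropeptides (0.034), proteasome (0.0066), translation factors (-0.016) and odorant-binding proteins (0.0050). With block medians they were those of channels (-0.048), GABA and glutamate (0.015), phototransduction (0.048), fat body (0.0092), translation factors (-0.020) and cuticle proteins (0.0089). With cameraPR they were those of the synaptic vesicle cycle (-0.0023), channels (-0.049), GABA and glutamate (0.0017), neuropeptides (0.030), clock (-0.030), muscle (0.042), fat body (0.087) and proteasome (0.14). With scaling they were those of channels (-0.0010), GABA and glutamate (0.037) and heat shock (0.020), and with spots over 3 left out those of muscle (0.093) and odorant-binding proteins (0.0068). No paired analysis was possible beyond the one-sample fit of ratios, which already pairs the 2 pools of a set, because each array holds 1 treated and 1 control pool.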

Other observations

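The test of other genes of the pentose phosphate and purine pathways was fixed before its result was seen, and the count of sign patterns after. Among list members outside the named ones, the mitochondrial ribosomal protein gene mRpL54 stood at 0.53 on 3 arrays and eIF3g1, a subunit of translation initiation factor eIF3, at 0.37 on 4. Obp19b, an odorant-binding protein, stood at -0.54 and at -0.32 without replicate 4, and Cpr49Ac, a cuticle protein, at -0.54 on 3 arrays. The acetylcholinesterase gene Ace stood at -0.59 on 3 arrays, of which replicate 3 was above 0, at -0.26 without replicate 2 and at -1.04 without replicate 3. With the values as deposited mRpL54 stood at -0.41, eIF3g1 at -0.00025 and Obp19b at 0.12. Their sign against 0 thus rests on the direction taken for the ratio. The median over all tested features was -0.17 as deposited, so eIF3g1 lay above most features there as well. None of them passed adjusted p 0.05 in limma.

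The count of 105 features at an unadjusted p under 0.05 was set against the 8 sign patterns of the 4 arrays. Of these, 5 gave as many, that of the likely direction included, and the highest count was 761, for the pattern that leaves every array as deposited. With 8 patterns a share under 0.05 cannot be reached. The highest count holds the offsets of the arrays, as the deposited medians of all 4 were below 0. Under the other reading of the deposited values it is the count for the treatment. With arrays centred that pattern gave 464 against 173 for the likely direction, so whole-array offsets are not all of it. With the local median subtracted it gave 293 against 236. Trends over the slide surface, a gene-specific dye bias and a drug effect cannot be told apart here.

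With Taldo and Paics among the named higher genes, a hypothesis was that other genes of the pentose phosphate pathway and purine synthesis rose as well. On all 4 arrays 3 of them were measured, CG8036, Adss and CG2767, and the place of CG2767 in these pathways is uncertain. Their mean shift against all genes was -0.0836 with a 95% interval of -0.36 to 0.19. The upper bound lay narrowly under the 0.2 set beforehand, which argues against a joint rise of that size in these 3 genes in the likely direction. For the 2 pathways it decides nothing. The 2 further genes, measured on 3 arrays each and not part of this test, were Adsl at 1.19 and Prat at -0.35, and the mean over all 5 was 0.14. Adsl was also among the 52 features whose orientation term passed, at -1.05 with a limma adjusted p of 0.0475, and with the values as deposited it stood at -1.33.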
